A study of Homo sapiens with 24 samples.

How the data were processed

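Libraries of T47D cells were prepared by ATAC-seq in 6 groups of 4. Per the processing notes the submitters gave, reads were trimmed with cutadapt 1.8.1, aligned with Bowtie2 2.4.4 and handled with SAMtools 1.9 on hg38. The peak caller, the counting tool, the handling of duplicates and any shift for the Tn5 insertion are not given in the sources used here. The deposited values are raw counts of reads or fragments per peak, in 1 peak set common to all 24 libraries, with no normalization. All are whole numbers, and no column was left out. The 189403 peaks are 200 to 958 bp wide (median 226 bp). Totals per library ran from 434598 to 12140005 counts, the second lowest being 2422981.

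Samples were grouped by their titles. The treatment label of 2 complete-medium vehicle libraries names fulvestrant, while title and description name DMSO, so results were also computed without these libraries. No library was left out otherwise. All 36 pairs of libraries within groups differed by more than sampling noise (chi-square per degree of freedom 1.73 to 3.81), so none was treated as a second run of another. The grouping, tests, gene lists, rule for named peaks and most alternatives were fixed before the data were examined. The split into replicates 1 and 2 against 3 and 4, its fits, leaving out the shallow libraries, the older edgeR fit and the ratio per library were added afterwards.

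All libraries entered a single edgeR 4.0.16 fit (R 4.3.3) with 6 group means. Peaks were filtered with filterByExpr (minimum count 10, minimum total 15), which kept 156745. Libraries were scaled by TMM, and contrasts were tested with the quasi-likelihood F-test (glmQLFit, legacy=FALSE, robust=TRUE), adjusted by Benjamini-Hochberg over all tested peaks at a threshold of 0.05. The tests are two-sided. The SE of a log2 fold change is its size over the root of F, an approximation. Fitted fold changes weigh libraries by depth, so with the shallow fulvestrant replicate 4 they can differ from the ratio of mean CPM. CPM values use the TMM-scaled totals, and log values a prior count of 2. A fit with the set of replicates as a term nested in medium, fits within each set, RLE factors, total counts, loess offsets (span 0.3, 4 iterations), no low-count filter, a filter at the median abundance, only the groups compared, the replicate number as a block, the older edgeR fit, DESeq2 1.42.0 and leaving out each library in turn served as alternatives.

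Gene symbols and intervals came from a table of 20056 protein-coding genes on GRCh38.p14 that gives no strand. Distances were therefore measured from the middle of a peak to the nearest edge of the gene's whole interval, in place of the planned distance to a transcription start, and a peak inside the interval has distance 0. The 13 gene lists held 151 entries for 150 genes, all matched, and a list's peaks are those within 50 kb of its genes (10 kb as an alternative). Camera in limma 3.58.1 tested 65 combinations of list and comparison with a preset correlation of 0.01, and with an estimated correlation as an alternative, adjusted over all 65. Fisher's exact test compared the share of called peaks in a list with that of all other tested peaks, in the estradiol and the media comparisons. It treats peaks as independent, which peaks near the same gene are not, so its p-values can be too small. A reference genome was not used here, so the planned motif lists and correction for GC content were not run.

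The estradiol-raised set is every peak called higher with estradiol, chosen in starved libraries and tested by camera in the complete-medium ones, adjusted over 12 tests together with the estradiol-lowered set. The ratio per library is the log2 ratio of the mean count per peak of the set to that of 6032 peaks of matched abundance called for neither estradiol nor medium. Its differences were tested with an exact permutation test over all splits of 4 against 4 (smallest p 0.0286), and the 97.1% interval comes from the pairwise differences between libraries. Agreement between antagonists was set against 10 simulated groups without effect that share the same vehicle libraries, and computed again with separate pairs of vehicle libraries.

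Peaks named in the text follow a rule. For comparisons with a vehicle or between media, they are up to 10 rises and 10 falls with the largest log2 fold change among called peaks above the median abundance whose 4 libraries of one group all lie on 1 side of the other 4. For each gene of the first 5 lists the peak with the smallest p within 50 kb was also eligible, with 2 to 4 given per list, and for pairs of antagonists the 5 peaks with the smallest p. Peaks on chromosome Y or unplaced contigs were not named. Peaks outside the rule are marked as chosen after their values were seen.

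The pipeline was tested on simulated data with the depths of these libraries. In the estradiol comparison it called 8.96% of peaks changed 1.5-fold, 40.3% of those changed 2-fold and 75.8% of those changed 4-fold, and 17.6%, 73.5% and 100% in the upper part of abundance. In the fulvestrant comparison these values were 10.4%, 32.8% and 78.8%, and 20.6%, 67.9% and 97.2%. Of 102 and 90 calls, 19 and 9 were false, in both cases a larger share than the threshold of 0.05 aims at. Calls close to the threshold may thus be false more often than it states. Of unchanged peaks, 6.06% and 5.84% had an unadjusted p under 0.05. A set of 500 peaks lowered to 0.85-fold in the fulvestrant group was recovered at 0.843-fold. Camera gave an unadjusted p of 9.51e-10 for that set and of 0.925 for an unchanged one. Peaks were simulated as independent and without the replicate sets, while the estradiol-raised set had an estimated correlation of 0.311. The simulation therefore does not test camera's preset correlation of 0.01 for such a set. The median SE of the log2 fold change over all tested peaks was 0.301 for estradiol, 0.326 for fulvestrant, 0.302 for raloxifene, 0.31 for tamoxifen and 0.312 between media. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.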

Results

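Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin. The cells were T47D, an established human breast cancer line of luminal type that expresses the estrogen receptor. The deposited table holds counts in 189403 peaks of genome build hg38 for 24 libraries, 4 in each of 6 groups. Cells of 4 groups stood for 1 day in complete medium and then received for 1 h either vehicle (0.1% DMSO) or 100 nM of fulvestrant, raloxifene or tamoxifen. Cells of the other 2 groups stood for 3 days in hormone-starved medium (no phenol red, serum stripped with charcoal) and then received for 1 h vehicle or 1 nM estradiol. Fulvestrant is a steroid derived from estradiol that carries a long side chain and leads to loss of the receptor. Raloxifene, a benzothiophene, and tamoxifen, a triphenylethylene, are selective estrogen receptor modulators. In complete medium, the vehicle libraries of replicates 3 and 4 carry fulvestrant in one label and DMSO in their titles and descriptions, and were grouped by the title.

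Total counts in peaks for replicates 1 to 4 in complete medium were 9618550, 7771382, 10225935 and 7117770 with vehicle. With fulvestrant they were 11262408, 8553131, 5448411 and 434598, with raloxifene 10218691, 9367350, 8967836 and 7772169, and with tamoxifen 8065848, 6725045, 7489274 and 9871575. In starved medium they were 9011203, 8400820, 2422981 and 11336954 with vehicle and 8341632, 9707487, 12140005 and 7938382 with estradiol. Fulvestrant replicate 4 had no count in 36.1% of peaks, and starved vehicle replicate 3 in 12.96%. Of all peaks, 156745 passed the count filter and were tested. Replicates 1 and 2 differed from replicates 3 and 4 within groups in 9717 peaks, of which 3060 were higher and 6657 lower in replicates 3 and 4 (edgeR). The labels name no batch, and all 6 groups have 2 libraries in each set, so every comparison was repeated within each set and with the set as a term. Peak positions are given as in the deposited table, which does not state whether starts count from 0 or 1, and genes are the nearest protein-coding ones, except that peaks of the gene lists carry the name of a list gene within 50 kb, which need not be the nearest. Each value below has n = 4 per group unless stated. Nothing in the labels shows that the replicates are separate cultures, so p-values measure the spread between these libraries, and intervals on counts cover counting error only.

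Estradiol opened chromatin at far more sites than it closed. In starved cells, 1274 peaks gained and 35 lost accessibility after 1 h (edgeR, adjusted p under 0.05), with a median log2 fold change of 1.45 among the gains and -1.003 among the losses. Within PGR, which encodes the progesterone receptor, a peak (chromosome 11, 101034171 to 101034404) rose from 13 ± 1.93 to 39.4 ± 2.3 CPM (counts scaled to a common library size; SD, n = 4), a log2 fold change of 1.61 (SE 0.137, edgeR adjusted p = 1.48e-14). A peak within GREB1, a coactivator of the receptor and an early estrogen target (chromosome 2, 11531048 to 11531281), rose from 5.92 ± 1.21 to 23.3 ± 3.19 CPM, by 2.03 on the log2 scale (SE 0.179). Among well-covered peaks, some of the steepest fitted rises lay within the prostaglandin receptor gene PTGER3 (chromosome 1, 70915420 to 70915718, log2 fold change 3.31, SE 0.371) and within the immune checkpoint gene CD276 (chromosome 15, 73710153 to 73710447, 3.30, SE 0.442).

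Rises of 3.08 to 3.19 on the log2 scale were fitted 63.1 kb from KCTD15, 76.2 kb from ZNF706, 505 kb from CITED2 and 241 kb from the homeobox gene MSX2. At a peak 127 kb from KCNU1 (chromosome 8, 37063330 to 37063605), 140 counts with estradiol stood against 1 count with vehicle, a ratio of 114 with a 95% counting interval of 20.2 to 4550. The losses were shallower. A peak within ELOVL5, a fatty acid elongase gene (chromosome 6, 53325853 to 53326053), fell from 7.26 ± 1.42 to 4.03 ± 0.43 CPM (log2 fold change -0.90, SE 0.206). Peaks also fell within GLRX3, a glutaredoxin gene (chromosome 10, 130179675 to 130179935, -1.003, SE 0.264), within KLHDC1 (chromosome 14, 49721809 to 49722126, -0.93, SE 0.222) and 149 kb from FOXP1, a forkhead factor gene (-0.91). These calls were lost under 5 alternatives for ELOVL5, 10 for GLRX3, 7 for KLHDC1 and 7 for FOXP1. At least 2-fold changes made up 960 of the gains and 18 of the losses. Of the gained peaks 48.7% lay inside a gene, against 48.2% of all tested peaks.

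The gains gathered near genes known to be induced by estrogen. Within 50 kb of the 30 genes of that list, 57 of 661 peaks rose and 0 fell, and 21 genes had at least 1 rising peak while 9 had none. Adjusted over the list alone, 128 peaks rose and 1 fell. The share of rising peaks was 8.62% against 0.78% elsewhere (Fisher's exact test, odds ratio 12, adjusted p = 6.14e-38). Here and below, that test counts peaks near the same gene as independent, so its p-values can be too small. Examples beside PGR and GREB1 are the peaks 36 kb from the adenylate cyclase gene ADCY9 (chromosome 16, 4152339 to 4152569, log2 fold change 1.83, SE 0.159) and within the retinoic acid receptor gene RARA (chromosome 17, 40322369 to 40322630, 1.28, SE 0.114). The list as a whole shifted upward with camera's preset correlation (adjusted p = 7.22e-15), a call lost with an estimated correlation (adjusted p = 0.989). Near luminal identity genes, 18 of 544 peaks rose and 1 fell (29 and 5 adjusted over the list alone). Rising peaks lay near 8 of the 18 genes, and 3 of the 18 peaks are shared with the estrogen-induced list. They include the peaks 3.82 kb from MLPH (1.67, SE 0.193), within the epithelial factor gene GRHL2 (1.92, SE 0.221), 1.63 kb from the keratin gene KRT8 (0.77, SE 0.123) and 40.4 kb from ESR1, the gene of the estrogen receptor itself (1.09, SE 0.164). The falling one lay near FOXA1 (-2.48, SE 0.618). The rising share exceeded that of other peaks (Fisher's exact test, odds ratio 4.22, adjusted p = 8.37e-06), whereas camera called no shift of the list (adjusted p = 0.788).

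In the 11 other lists, few peaks changed with estradiol and camera called no shift. Of 157 peaks near glucocorticoid and progestin responsive genes, 2 rose, also 2 adjusted over the list alone, 46.6 kb from the chaperone gene FKBP5 (log2 fold change 1.23, SE 0.253) and within the transcription factor gene ZBTB16 (0.94, SE 0.219), with camera adjusted p = 0.929. Of 91 near aryl hydrocarbon receptor targets, 1 rose (3 adjusted over the list alone), 36.7 kb from TIPARP (1.02, SE 0.15), with camera adjusted p = 0.962. Near replication and cell cycle genes 7 of 218 rose (13 adjusted over the list alone), beside CDC6, CDT1 and TOP2A, but 6 of the 7 also lie near estrogen-induced genes. Their share exceeded that of other peaks (Fisher's exact test, adjusted p = 0.0128) and camera gave an adjusted p of 0.622. Peaks near immediate early genes (2 of 233, both near MAFF, camera adjusted p = 0.884), sterol synthesis genes (1 of 160, near SC5D, 0.876) and unfolded protein response genes (1 of 129, near ATF4, 0.876) rose in the same numbers over the list alone. No peak changed near estrogen-repressed genes (0 of 102, adjusted p = 0.731), interferon-stimulated genes (0 of 86, 0.921) or housekeeping genes (0 of 164, 0.903) in edgeR. Of the markers of other cells, blood cell genes had 0 of 65 changed peaks (0.962), and basal and mesenchymal genes had 2 of 126 rising near KRT14 (0.903), both shared with the estrogen-induced list, with 3 rising and 1 falling over that list alone.

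Within replicates 1 and 2, 907 peaks rose and 27 fell with estradiol, and within replicates 3 and 4, 729 rose and 26 fell. With the set as a term 1596 rose and 88 fell, 1309 of the calls without that term among them, and DESeq2 called 1127 and 13. The count of falls was 8 with edgeR's older dispersion estimate and ranged from 16 to 54 when 1 library was left out, with the largest shifts without starved vehicle replicate 2 (16), estradiol replicate 4 (19), estradiol replicate 1 (22) and estradiol replicate 2 (54).

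The vehicle libraries of both media answer how whole culture conditions differ, since days in medium (1 against 3) and seeding density differed along with hormone content. Complete medium had 12423 peaks higher and 15537 lower than starved medium, 17.8% of those tested (edgeR). A peak within PROM1, the gene of the stem cell surface protein CD133 (chromosome 4, 16002365 to 16002791), stood at 13.9 ± 3.44 CPM in complete and 0.57 ± 0.476 CPM in starved medium (log2 fold change 4.36, SE 0.31). A pair of peaks 263 and 265 kb from IMMP2L was higher by 4.70 and 4.68 (SE of the second 0.368), one 112 kb from the collagen gene COL12A1 by 4.10, one 244 kb from PIK3R1, a subunit of PI3-kinase, by 3.98, and the CD276 peak that estradiol raised by 3.89. The peak 127 kb from KCNU1 held 143 counts against 1, a ratio of 128 (95% counting interval 22.7 to 5100). In the other direction, a peak within SYT1, a synaptic vesicle protein gene (chromosome 12, 79383014 to 79383288), stood at 0.721 ± 0.238 CPM against 9.14 ± 4.3 CPM (-3.77, SE 0.358). Peaks 4.52 kb from the magnesium transporter gene SLC41A2 (-3.52) and within the DNA repair gene FANCD2 (-3.00) were also lower. So was a peak on chromosome 8 (89100826 to 89101237, -2.91) whose nearest gene, which need not be close, is the kinase gene RIPK2.

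Near estrogen-induced genes, 217 of 661 peaks were higher and 21 lower in complete medium (245 and 26 adjusted over the list alone). All 30 genes had a higher peak, and 14 of them a lower one as well. The higher share was 32.8% against 7.82% elsewhere (Fisher's exact test, odds ratio 5.76). Examples are peaks within the kinase gene SGK3 (chromosome 8, 66713944 to 66714185, 51.9 ± 1.31 against 8.15 ± 2.3 CPM, log2 fold change 2.54, SE 0.136) and within GREB1 (chromosome 2, 11531048 to 11531281, 2.59, SE 0.169). Near luminal identity genes 85 of 544 were higher and 24 lower (90 and 27 adjusted over the list alone), among them MLPH (2.63, SE 0.173) and GRHL2 (2.41, SE 0.185). Near replication and cell cycle genes 35 of 218 were higher and 14 lower (36 and 14 over the list alone), with 16 of the 35 shared with the estrogen-induced list. Camera called these 3 lists upward with its preset correlation (adjusted p = 4.84e-11, 0.0499 and 0.0499) and none of them with an estimated correlation (adjusted p = 0.989 for each). Near glucocorticoid and progestin responsive genes, 26 of 157 were higher and 7 lower, also over the list alone. They include ZBTB16 (2.71, SE 0.175), FKBP5 (2.07, SE 0.227) and the phosphatase gene DUSP1 (-1.50, SE 0.245), with camera adjusted p = 0.0625 and Fisher's exact adjusted p = 0.002.

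In the other lists peaks went both ways between the media and camera called no shift. Aryl hydrocarbon receptor targets had 12 higher and 8 lower of 91 (13 and 10 adjusted over the list alone, camera adjusted p = 0.962), with a peak 6.09 kb from the quinone reductase gene NQO1 at 2.08 and one near the receptor's repressor gene AHRR at -0.95. Estrogen-repressed genes had 4 higher and 9 lower of 102 (4 and 6 over the list alone, 0.962), with ERBB2 at -0.75 (SE 0.121) and the cyclin gene CCNG2 at -0.97. Immediate early genes had 16 higher and 22 lower (15 and 22, camera adjusted p = 0.884), sterol synthesis genes 13 and 10 (10 and 10, 0.731), unfolded protein response genes 11 and 9 (11 and 9, 0.941), interferon-stimulated genes 6 and 8 (6 and 8, 0.941) and housekeeping genes 14 and 7 (14 and 7, 0.59), each second pair being the counts over the list alone. Blood cell markers had 4 higher and 9 lower (4 and 9, 0.378), and basal and mesenchymal markers 12 and 15 (14 and 16, 0.962). The media differed in 8746 higher and 11191 lower peaks within replicates 1 and 2, and in 4293 and 6270 within replicates 3 and 4. The set as a term gave 14181 and 17305, leaving out both vehicle libraries with conflicting labels 8570 and 9320, and DESeq2 8530 and 12183.

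Most of the sites that estradiol opened were also more open in complete medium. Of the 1274 gained peaks, 1008 (79.1%) were higher in complete than in starved vehicle cells, and 6 were lower. Of the 35 lost peaks, 23 were lower in complete medium and 0 were higher in edgeR. The comparisons share the starved vehicle libraries, so these libraries were also split 6 ways, with 2 used to choose the raised set and the other 2 to test it, while the overlap of the lost peaks has no such control. The chosen set then held 512 to 892 peaks, with a median log2 fold change of 1.36 to 1.47 between the media and 62.2% to 82.6% of its peaks higher. Camera's p stayed at or below 9.66e-70 with the preset and ran from 0.00107 to 0.00416 with an estimated correlation in limma. Conversely, 8.11% of the peaks higher in complete medium were among those that estradiol raised.

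**Figure D1:**
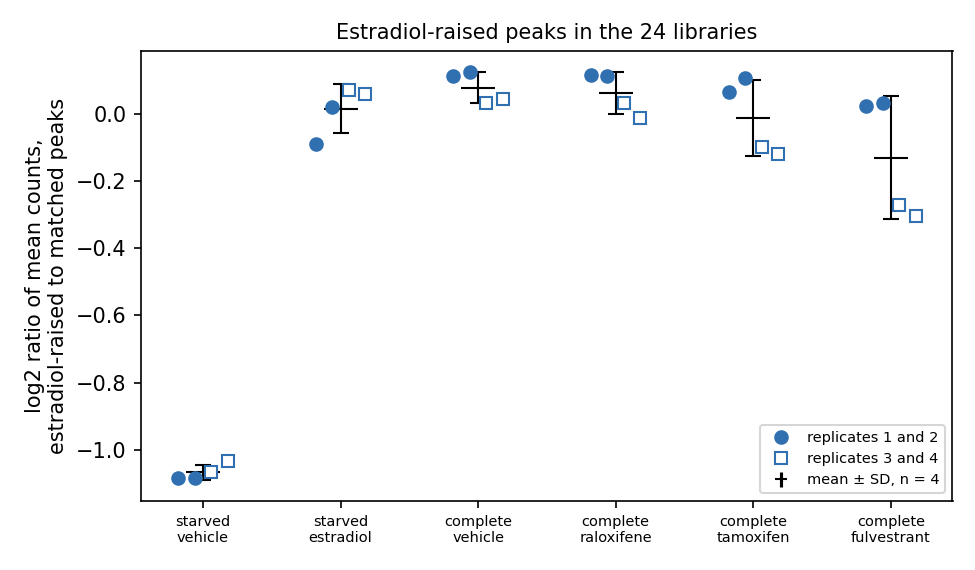
Log2 ratio of mean counts in the 1274 estradiol-raised peaks to those in 6032 peaks of matched abundance, 1 point per library (circles replicates 1 and 2, squares replicates 3 and 4), with the mean and SD of each of the 6 groups. Starved vehicle lies at -1.07 ± 0.0234 and the other groups between -0.13 and 0.08, with fulvestrant lowest of those in complete medium.

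Fulvestrant left no single peak past the threshold. The estradiol-raised peaks lay lower as a set, a shift that was called with camera's preset correlation and not with an estimated one. In edgeR 0 peaks were called either way, with 6212 at an unadjusted p under 0.05, and DESeq2 called 0 (4820 unadjusted). The estradiol-raised set had a median log2 fold change of -0.16 against vehicle, and 77.2% of its peaks lay below 0. As a ratio per library, the set stood at -0.13 ± 0.183 with fulvestrant and 0.08 ± 0.0464 with vehicle, a difference of -0.209 or 0.865-fold (97.1% interval -0.43 to -0.00134). The peak within GREB1 with the smallest p (chromosome 2, 11532540 to 11532845) stood at 7.45 ± 5.62 with fulvestrant and 18.2 ± 4.46 CPM with vehicle (log2 fold change -0.87, SE 0.257, edgeR adjusted p = 1). Near other estrogen-induced genes, values were -0.53 (SE 0.141) 0.058 kb from the receptor kinase gene RET, -0.78 near the factor gene XBP1 and -0.31 within SGK3, none past the threshold.

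Camera called the set lower with fulvestrant (adjusted p = 7.96e-11 over 12 tests), a call lost with an estimated correlation (adjusted p = 0.792), and 15 of its peaks were lower when adjusted over the set alone. The exact permutation p of the ratio was 0.0286, the smallest possible with 4 against 4, and 0.172 adjusted over the 6 antagonist comparisons. Permuted within the replicate sets it was 0.0556, the smallest that exact test allows. Peaks higher in complete medium that estradiol did not change lay at -0.0768 with fulvestrant, -0.109 with raloxifene and -0.12 with tamoxifen, but they were chosen as high in the same vehicle libraries, which lowers them under every antagonist, so these values do not show whether a fall is particular to the estradiol-raised peaks. The ratio, chosen after the data were seen, differed by -0.0902 in replicates 1 and 2 and by -0.327 in replicates 3 and 4, and by -0.15 without the shallow replicate 4. With the set of replicates as a term in edgeR, 4 peaks fell and 0 rose, and all 4 were among those estradiol raised (0.033 expected). They lie within GREB1 (the same peak, -1.02, SE 0.153), within THSD4 (chromosome 15, 71104647 to 71104989, -0.99, SE 0.174), 304 kb from SOX5 (chromosome 12, 23225839 to 23226076, -1.05, SE 0.205) and 125 kb from STC2 (chromosome 5, 173453231 to 173453461, -0.64, SE 0.121), the last 3 chosen after their values were seen. Replicates 1 and 2 alone gave 1 fall, the same GREB1 peak (-0.91, SE 0.166), and replicates 3 and 4 alone 73 rises and 15 falls, with 12 of the falls and 0 of the rises among the estradiol-raised peaks. Without the shallow replicate 4 the latter became 21 rises and 18 falls in edgeR, 16 of the falls and 0 of the rises being estradiol-raised, a fit in which the lone fulvestrant library is assumed to vary like the other groups. With both fulvestrant libraries of replicates 3 and 4, the rises lay at lower abundance (median log2 CPM 1.48) than the falls (3.74). In the full fit only 1274 of 156745 tested peaks were estradiol-raised, so finding 0 of them among so few rises says little. Among the 15 falls, 0.12 were expected. Among the 13 lists, estrogen-induced genes came nearest to a call (661 peaks, 0 called and 0 adjusted over the list alone, median -0.072, camera adjusted p = 0.0564, 0.0386 within 10 kb and 0.989 with an estimated correlation), and the 35 estradiol-lowered peaks were not called (0.603).

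Raloxifene raised 1 peak. It lies within TGIF2, a homeobox repressor gene of TGF-beta signalling (chromosome 20, 36587377 to 36587616), and rose from 9.75 ± 0.495 CPM with vehicle to 17.5 ± 2.43 CPM (log2 fold change 0.85, SE 0.15, edgeR adjusted p = 0.041). The same peak stood at 2.03 ± 0.684 CPM in starved vehicle and 9.84 ± 1.73 CPM in estradiol-treated cells. No peak fell in edgeR, 5971 had an unadjusted p under 0.05, and DESeq2 called 0 (3627 unadjusted). The estradiol-raised set did not differ detectably from vehicle, with a median of 0.01 (camera adjusted p = 0.593) and a difference of the ratio of -0.0159 (97.1% interval -0.136 to 0.081, exact permutation p = 0.629, and 0.278 permuted within the replicate sets). Without the vehicle libraries with conflicting labels the difference was -0.0557 for raloxifene, -0.248 for fulvestrant and -0.13 for tamoxifen. These values set all 4 libraries of an antagonist against vehicle replicates 1 and 2 alone. They therefore also hold the difference between the replicate sets. None of the 13 lists was called (smallest adjusted p = 0.59), with 0 peaks called near any of them and 0 adjusted over the list alone. Near estrogen-induced genes, the smallest p belonged to a peak 30.7 kb from the chemokine gene CXCL12 (-0.44, SE 0.143, edgeR adjusted p = 1). The TGIF2 call was lost in each set of replicates alone and without any 1 of 7 of the 8 libraries (it held without raloxifene replicate 4). With the set as a term it stood at 0.84 (edgeR adjusted p = 0.00203) and a peak 25.7 kb from MINDY4B joined it (chromosome 3, 150844557 to 150844788, 1.32, SE 0.251), chosen after its values were seen.

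Tamoxifen changed no single peak past the threshold. EdgeR called 0 (6479 at an unadjusted p under 0.05) and DESeq2 0 (4205 unadjusted). The estradiol-raised set had a median of -0.07 with 65.7% of peaks below 0, and its ratio stood at -0.01 ± 0.114 against 0.08 ± 0.0464 with vehicle, a difference of -0.0905 (97.1% interval -0.245 to 0.0719, exact permutation p = 0.286). Camera called the set lower (adjusted p = 0.0257), a call lost with an estimated correlation (adjusted p = 0.792) and without vehicle replicate 1, vehicle replicate 2, tamoxifen replicate 3 or tamoxifen replicate 4 (adjusted p up to 0.577). The differences in ratio were -0.0331 in replicates 1 and 2 and -0.148 in replicates 3 and 4, and the exact permutation p within the replicate sets was 0.0556, the smallest possible. Near estrogen-induced genes, values with the smallest p were -1.98 (SE 0.52) near the carbonic anhydrase gene CA12, -1.46 (SE 0.44) near IGFBP4 and -0.60 (SE 0.212) near TFF1, all with an edgeR adjusted p of 1. Of the 13 lists, camera called blood cell markers upward (65 peaks, 0 called and 0 adjusted over the list alone, median 0.06, adjusted p = 0.0295), a call lost with an estimated correlation (adjusted p = 0.989) and within 10 kb (adjusted p = 0.183). Replicates 1 and 2 alone gave 1 rise, within DIP2C (chromosome 10, 436545 to 436996), chosen after its values were seen, and replicates 3 and 4 alone and the set as a term gave 0.

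**Figure D2:**
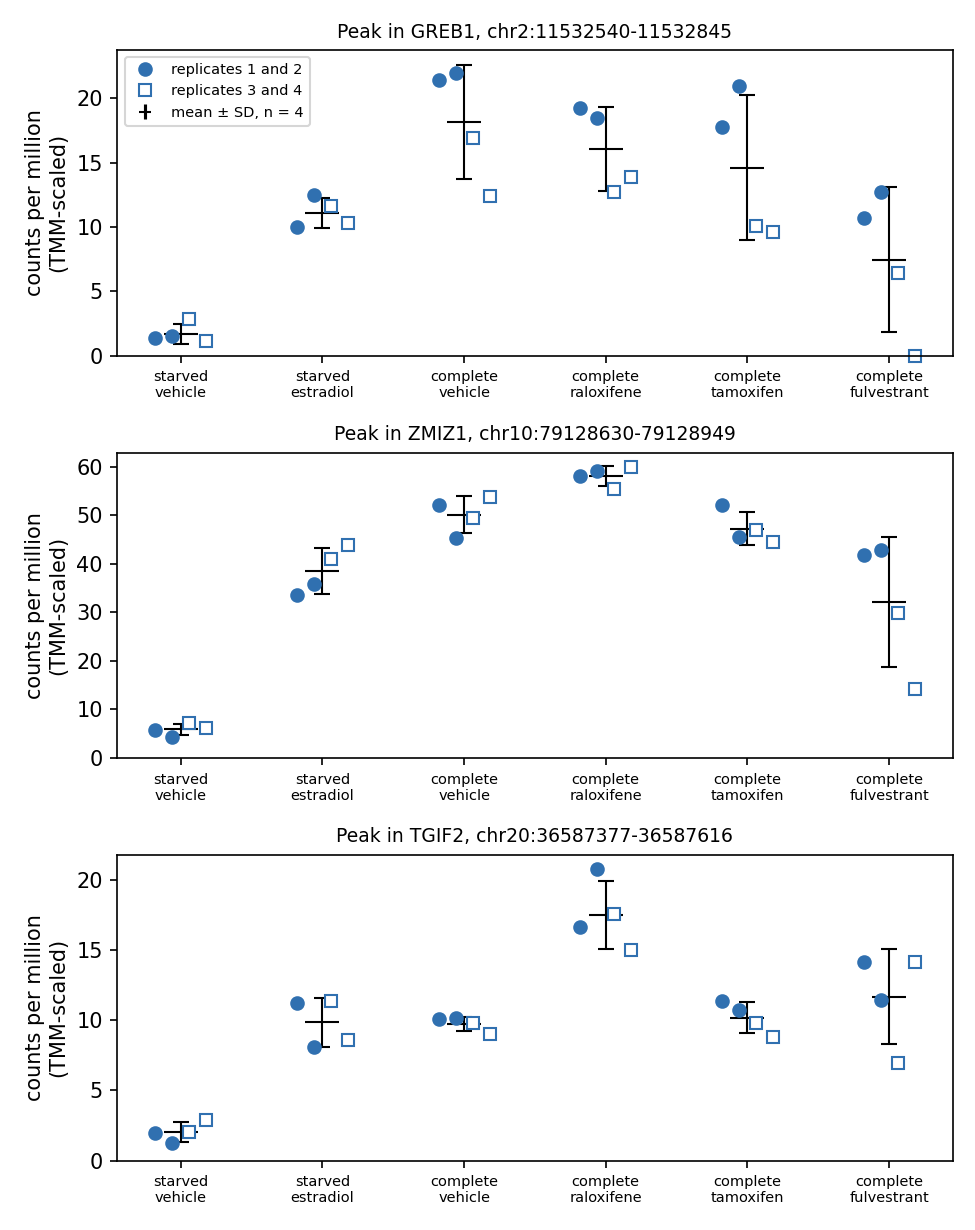
CPM, scaled by TMM, of the GREB1 peak of the fulvestrant comparison and the ZMIZ1 and TGIF2 peaks, 1 point per library (circles replicates 1 and 2, squares replicates 3 and 4) with the mean and SD of each of the 6 groups. The ZMIZ1 peak averages 32.1 with fulvestrant and 58.1 with raloxifene, and the TGIF2 peak 17.5 with raloxifene and 9.75 with vehicle.

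The 3 antagonists were then compared with each other at the same dose (100 nM) and time (1 h). The steroidal ligand, fulvestrant, differed from the benzothiophene, raloxifene, at 1 peak. It lies within ZMIZ1, a transcriptional coactivator gene (chromosome 10, 79128630 to 79128949), and stood at 32.1 ± 13.4 CPM with fulvestrant and 58.1 ± 2.02 CPM with raloxifene (log2 fold change -0.61, SE 0.109, edgeR adjusted p = 0.0411). Vehicle cells had 50.2 ± 3.72 CPM there in complete medium and 5.88 ± 1.19 CPM in starved medium. The next smallest p belonged to a peak within CASTOR2 (chromosome 7, 75000932 to 75001228, -1.15, edgeR adjusted p = 0.063). DESeq2 called 0 peaks (7018 unadjusted, 8093 in edgeR), and the ZMIZ1 call was lost without fulvestrant replicate 1 or 3 or any 1 raloxifene library. With the set as a term, 7 peaks were lower with fulvestrant and 0 higher, among them ZMIZ1 (-0.62), CASTOR2 (-1.26) and GREB1 (-0.83), and 6 of the 7 were among those estradiol raised (0.057 expected). Within replicates 1 and 2 edgeR called 0 peaks, and within replicates 3 and 4 it called 112 higher and 20 lower, or 40 higher and 30 lower without fulvestrant replicate 4.

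Between fulvestrant and tamoxifen, the triphenylethylene, edgeR and DESeq2 each called 0 peaks (8267 and 7181 unadjusted), and the smallest p fell on a peak 39.1 kb from CYP2A7 (chromosome 19, 40921133 to 40921531, 41.2 ± 17.3 against 74.5 ± 9.12 CPM, log2 fold change -0.61, edgeR adjusted p = 0.472). The set as a term gave 3 lower peaks, that one among them (-0.62). The others lay 213 kb from GUCY1A2 (-0.97) and near NYAP2 (-0.80), chosen after their values were seen. Replicates 1 and 2 alone gave 2 lower peaks, and replicates 3 and 4 alone 268 higher and 13 lower, or 100 higher and 6 lower without fulvestrant replicate 4. The 268 higher peaks lay at low abundance (median log2 CPM 1.02, against 2.91 for the 13 lower ones). None of them was estradiol-raised, which says little, as only 1274 of 156745 peaks tested in the full fit were. Against raloxifene in replicates 3 and 4 these medians were 1.31 and 3.84. Between raloxifene and tamoxifen, edgeR and DESeq2 again called 0 (6147 and 3836 unadjusted), with the smallest p at the TGIF2 peak (0.80, edgeR adjusted p = 0.198). That peak was called with the set as a term (0.78, edgeR adjusted p = 0.0225), and either set of replicates alone gave 0 peaks.

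Over the estradiol-raised set, fulvestrant lay below raloxifene by a median of -0.18 (camera adjusted p = 7.96e-11) and below tamoxifen by -0.09 (3.55e-06), and raloxifene lay above tamoxifen by 0.09 (0.00305). All of these camera calls were lost with an estimated correlation (adjusted p = 0.792 for each), and the last also without raloxifene replicate 1, tamoxifen replicate 3 or tamoxifen replicate 4 (adjusted p up to 0.244). As a ratio per library the differences were -0.193 for fulvestrant against raloxifene (97.1% interval -0.42 to 0.0433, exact permutation p = 0.143), -0.118 for fulvestrant against tamoxifen (-0.411 to 0.153, p = 0.286) and 0.0746 for raloxifene against tamoxifen (-0.117 to 0.235, p = 0.286). They were -0.0866, -0.0571 and 0.0295 in replicates 1 and 2, and -0.299, -0.179 and 0.12 in replicates 3 and 4. Without the shallow fulvestrant replicate 4 the first 2 were -0.134 and -0.0598. These tests and intervals ignore the replicate sets. Permuted within the sets, the exact p was 0.0556 for each of the 3 differences, the smallest that such a test allows, so it cannot pass the threshold here. The 35 estradiol-lowered peaks gave no call between antagonists (camera adjusted p from 0.242 to 0.567).

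The antagonists share their vehicle libraries, which ties their peakwise changes together. Across peaks, which are not independent replicates, log2 fold changes of fulvestrant and raloxifene had a covariance of 0.0324 against 0.0473 in groups simulated without any effect, those of fulvestrant and tamoxifen 0.0348 against 0.0474, and those of raloxifene and tamoxifen 0.0466 against 0.0471. With separate pairs of vehicle libraries for each antagonist the covariances were -0.0136, -0.0112 and 0.000667 on average over 6 ways of pairing, and the correlations ran from -0.148 to 0.0159, from -0.137 to 0.0317 and from -0.0198 to 0.0407. The simulated groups do not hold the replicate sets and the pairs can fall along them, so these values do not decide whether the antagonists share changes.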

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

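The tests of a mixture with starved cells, of low depth, of a general shift and of fulvestrant in the vehicle libraries were chosen after their results had been seen. Those of other splits of the libraries and the depth and interaction tests of the replicate sets were written before.

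Libraries that stood apart from the other 3 of their group were fulvestrant replicate 4, with a TMM factor of 1.558 and 36.1% of peaks without a count, and starved vehicle replicate 3, with a TMM factor of 1.048 and 12.96%. These are 4 of 48 combinations of group and measure, and chance sets about 1 in 20 apart. The ZMIZ1 peak drew attention because the effects of fulvestrant and raloxifene differed there by -0.612 on the log2 scale, tested by the contrast itself.

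Estradiol-raised peaks lay lowest with fulvestrant in replicates 3 and 4, at -0.327 below vehicle. A mixture with starved cells would lower all peaks that depend on complete medium, but those that estradiol did not change lay at -0.0591 (a value that their choice in the vehicle libraries tends to lower), short of the -0.164 that a mixture would need by more than the vehicle spread of 0.024. Low depth would spare the deeper replicate 3, yet it lay at -0.311, close to the -0.344 of replicate 4. In replicates 1 and 2 the difference was -0.0902, and raloxifene differed by -0.00354 there, short of the -0.0451 that a shift common to the antagonists needs but by less than the vehicle spread of 0.0464, so such a shift and an effect of fulvestrant cannot be told apart in these replicates. Tamoxifen, which was not part of this test, differed by -0.0331 in replicates 1 and 2. In replicates 3 and 4 tamoxifen differed by -0.148 and raloxifene by -0.0282. An effect of fulvestrant on estrogen-dependent sites may account for the pattern, as a hypothesis, and a difference in handling of single cultures was not tested.

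Replicates 1 and 2 stood apart from replicates 3 and 4 across the groups. Values argue against library depth as the whole cause, since 95.3% of the peaks called between them stayed called with offsets that follow abundance, and their totals overlap. Depth cannot be excluded by this, as the lowest totals (434598, 2422981 and 5448411) all lie in replicates 3 and 4. The comparison of the replicate sets was not repeated without those libraries. A treatment effect that differs between the replicate sets is not seen for estradiol, where the interaction called 0 peaks in edgeR against 1684 for estradiol itself. The interaction compares differences that rest on 2 libraries per group in each set, so it can miss changes of a size that estradiol itself shows. It was not fitted for the antagonists. A batch of culture, library preparation or sequencing stays open, as the labels name none, and no biological explanation was tested.

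The labels of vehicle replicates 3 and 4 conflict. Had these libraries received fulvestrant, their estradiol-raised ratio would match fulvestrant replicates 3 and 4, but it lay 0.327 above them and 0.0282 from raloxifene of the same replicates, with a vehicle spread of 0.0464. Their mean ratio of 0.0389 was also close to the 0.0284 of fulvestrant replicates 1 and 2, and below the 0.119 of vehicle replicates 1 and 2. Those libraries belong to the other replicate set, so the ratio is a weak check of the label. A wrong entry in one label remains possible, and the ratio speaks only to a ligand that acts like fulvestrant did in replicates 3 and 4.

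Other splits of the 8 libraries into 4 and 4 were fitted in 35 ways for each comparison, with only those libraries in the fit. Between the media only 1 of the 35 splits, the real one, gave as many peaks (28456, highest other 10), the smallest share these splits allow. The other splits mix the media and carry the media difference as spread, which lowers their counts. This argues against chance but cannot exclude it alone. For estradiol 2 splits, the real one included, gave at least the real count, and chance cannot be excluded by this count alone. The split into replicates 1 and 2 against 3 and 4 gave 2119 peaks against 1308, while the highest of the rest gave 22. Within the replicate sets estradiol raised 907 and 729 peaks. Chance cannot be excluded for raloxifene, where 6 splits gave at least the real 2 peaks (highest 820, by replicate set, then 72). Where the real split gave 0 peaks in edgeR, all 35 splits necessarily give as many, so the count says nothing about chance. There the highest others were 447 for fulvestrant (by replicate set 113), 1419 for tamoxifen, 566 for fulvestrant against raloxifene, 1336 for fulvestrant against tamoxifen and 2856 for raloxifene against tamoxifen, the last 4 by replicate set. Counts this far above the real ones point to a structure of the samples. The 447 came from vehicle replicates 1 and 3 with fulvestrant replicates 1 and 2 against the remaining libraries. That split follows depth, since the lowest total on the first side (8553131) exceeded the highest on the other (7771382). Within the replicate sets, edgeR called for fulvestrant 1 and 88 peaks, for raloxifene 0 and 0, for tamoxifen 1 and 0, for fulvestrant against raloxifene 0 and 132, for fulvestrant against tamoxifen 2 and 281, and for raloxifene against tamoxifen 0 and 0. Without the shallow fulvestrant replicate 4, the 88, 132 and 281 peaks became 21 higher and 18 lower, 40 higher and 30 lower, and 100 higher and 6 lower.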

How the results depend on the processing

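Fits with the replicate sets, without the shallow libraries or with the older edgeR estimate, and set tests that join them with an estimated correlation, were added after the data were seen. No called result turned its direction. The covariances of fulvestrant with either other antagonist turned negative with separate vehicle libraries on average over 6 pairings, though the correlations of single pairings lay on both sides of 0 (-0.148 to 0.0159 with raloxifene, -0.137 to 0.0317 with tamoxifen), and of the named peaks 2 values for fulvestrant and 1 for raloxifene, none of them called, changed sign. Of the values of the main results, 302 counted as unchanged under alternatives fixed beforehand and 85 under added ones, 45 and 39 moved, and 12 and 10 lost their call. Unchanged counts and covariances stayed near their size, and a count of 0 that stayed 0 is among them. For set tests, unchanged means only that p stayed on the same side of the threshold, whatever its size. Estradiol rises ranged from 954 to 1210 without 1 library (1274 in full) and were 729 in replicates 3 and 4 alone. Falls (35 in full) were 21 with only the groups compared, 88 with the batch term, 8 with the older estimate, 13 in DESeq2 and 16 to 54 without 1 library. Between media, replicates 3 and 4 alone gave 4293 higher and 6270 lower, leaving out the vehicles with conflicting labels 9320 lower, and leaving out 1 library 9130 to 12663 and 12247 to 15500. Fulvestrant gave 4 falls with the batch term, 1 in replicates 1 and 2 alone, and 73 rises and 15 falls in replicates 3 and 4 alone. The raloxifene rise became 0 with total counts, no low-count filter, without the conflicting vehicles, in replicates 1 and 2 alone, in replicates 3 and 4 alone, with the older estimate and in DESeq2, became 2 with only the groups compared and with the batch term, and ranged from 0 to 1 without 1 library. Tamoxifen gave 1 rise in replicates 1 and 2 alone. Fulvestrant against raloxifene (1 in full) gave 0 with no low-count filter, only the groups compared, replicates 1 and 2 alone, the older estimate and DESeq2, 7 with the batch term, 132 in replicates 3 and 4 alone, and 0 to 1 without 1 library. Fulvestrant against tamoxifen (0 in edgeR in full) gave 1 with loess offsets, 3 with the batch term, 2 in replicates 1 and 2 alone, 281 in replicates 3 and 4 alone, 1 without the shallow libraries and 0 to 1 without 1 library (1 without fulvestrant replicate 2). Raloxifene against tamoxifen gave 1 with only the groups compared and 1 with the batch term. Fewer libraries enter the fits within replicate sets and those of only the groups compared. For the other changes the cause was not tested.

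Replicates share only a number across groups. Deviations from group means correlated from -0.128 to 0.126 between same-numbered libraries, with 7 of 60 pairs above 0.1. On average 16 of 24 libraries correlated best with their own number, but all 24 did so with a number of their own replicate set. The median correlation was 0.0526 for the same number, 0.0419 for the other number of the same set and -0.048 for the other set. These values follow the replicate sets and are at most a weak hint of pairing by number, from the data and not the design. The replicate block moved the falls with estradiol to 74, those with fulvestrant to 4 and the raloxifene rises to 2. Fulvestrant against raloxifene moved to 6, fulvestrant against tamoxifen to 3 and raloxifene against tamoxifen to 1. The block also called 1 gene list for fulvestrant, the estrogen-induced genes. With the preset correlation its camera adjusted p was 0.0412, against 0.0564 without the block, so the value only crossed the threshold. Without the block and with an estimated correlation it was 0.989. The block changed no other call among the counts, gene lists and set tests with the preset correlation.

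With an estimated correlation the estradiol-raised set lost each of its 5 calls (adjusted p = 0.792). That p was 0.814 with the batch term added, and with the replicate block added 0.801 for fulvestrant against vehicle, raloxifene and tamoxifen and 0.81 for tamoxifen against vehicle and raloxifene against tamoxifen. Without 1 library the p with the preset correlation ran from 0.000328 to 0.577 for tamoxifen and from 1.98e-05 to 0.244 for raloxifene against tamoxifen. Gene lists called with an estimated correlation were 0 for estradiol, tamoxifen and the media (1, 1 and 3 with camera's preset), and within 10 kb 1 for fulvestrant and 0 for tamoxifen. Covariances between antagonists rose to 0.0747, 0.0763 and 0.093 without the conflicting vehicles, where fewer shared vehicle libraries by themselves raise a covariance. With separate vehicle libraries for each antagonist the covariances were -0.0136, -0.0112 and 0.000667. Without 1 library they ran from 0.0262 to 0.0529, 0.0303 to 0.0547 and 0.0455 to 0.0685. The order is fulvestrant with raloxifene, fulvestrant with tamoxifen, raloxifene with tamoxifen. Among named peaks, 92 of 838 values for estradiol and 9 of 880 for the media lost their call under an alternative, and none of them turned. The estradiol losses bore most of these. They are named here by their nearest gene, which need not be close to the peak. Among them the call ended under 11 alternatives for LAMP1, 10 for GLRX3, 10 for MAN2A1, 9 for SORCS1 and 8 for NELL1. It ended under 7 for KLHDC1, 7 for FOXP1, 6 for CNTNAP5 and 5 for ELOVL5. Among the rises it ended under 6 alternatives for the ZBTB16 peak and 1 for the FKBP5 peak. Motif lists and correction for GC content were not run, as no reference genome was used. Depth limits what could be called: in simulated data about 40.3% of 2-fold changes passed for estradiol and 32.8% for fulvestrant. Of the simulated calls, 19 of 102 and 9 of 90 were false, a larger share than the threshold aims at.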

Other observations

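The comparison of replicates 3 and 4 with replicates 1 and 2 and its list tests were chosen after the data were seen, and all peaks named here were chosen after their values were seen. Over all 6 groups together, replicates 3 and 4 were more open at a cluster of peaks near HSPA8, which encodes the constitutive chaperone HSC70. These peaks lie 3.94 to 5.77 kb from the gene (chromosome 11, from 123051618 to 123053650) and were higher in replicates 3 and 4 by 2.06 to 2.55 on the log2 scale (SE 0.14 to 0.186, 12 libraries against 12). A peak 13.5 kb from MRFAP1L2 was higher by 1.06 (SE 0.0869). Peaks within the LDL receptor family gene LDLRAD3 (-0.74, SE 0.0636) and 67.3 kb from the zinc finger gene KLF6 (-0.94, SE 0.0814) were lower.

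Near immediate early genes, 26 of 233 peaks were lower and 2 higher in replicates 3 and 4, and camera called the list lower (adjusted p = 0.0497), a call lost with an estimated correlation (adjusted p = 0.975). Of the estradiol-raised peaks, 201 were lower and 29 higher (median -0.13, camera adjusted p = 1.08e-07, and 0.975 with an estimated correlation). By group, the mean ratio of the set in replicates 1 and 2 and in replicates 3 and 4 went from 0.0284 to -0.288 with fulvestrant, from 0.0854 to -0.109 with tamoxifen, from 0.115 to 0.0107 with raloxifene and from 0.119 to 0.0389 with vehicle in complete medium, but from -1.08 to -1.05 with vehicle and from -0.0335 to 0.0645 with estradiol in starved medium. A difference between groups in this shift of the set was not tested. Near luminal identity genes 48 of 544 peaks were higher and 16 lower, with no call of the list (camera adjusted p = 0.249), and near estrogen-induced genes 13 were higher and 52 lower (camera adjusted p = 0.145). Across the 1309 peaks called with estradiol, which are not independent replicates, the log2 fold change with estradiol correlated at -0.17 with that of fulvestrant, at 0.0952 with that of raloxifene and at -0.0653 with that of tamoxifen. Over all 156745 tested peaks the correlations were -0.0339, -0.00775 and -0.0224, so the value for raloxifene changed sign.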
